A study of Mus musculus with 16 samples.

How the data were processed

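Lung endothelial cells (EC), the cells that line the vessels of the lung, were profiled by single-cell RNA sequencing in female C57BL/6N mice. Per the labels, cells came from wild-type mice (d0), mice bearing a primary tumour (d15), mice whose tumour had been resected (d22) and mice bearing metastases (d36). The tumour-bearing mice had received Lewis lung carcinoma cells, a mouse lung tumour line, under the skin. Per the labels, EC were isolated by fluorescence-activated sorting and libraries were made with a 10x Genomics Chromium 3′ kit, version 2, which counts 3′ ends of transcripts with unique molecular identifiers (UMIs). The series' design text states that 10000 sorted EC went into library preparation and that 4 libraries were made from each sample. The labels list 16 samples, 4 libraries for each of the 4 days.

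The deposited table holds counts, the number of UMIs per gene and cell, as the authors' software wrote them and without scaling. The submitters' processing notes name Cell Ranger 2.1.1 and the mouse build mm10. The annotation release and any filter on cells are not given in the sources used here. All deposited cells had at most 10% mitochondrial UMIs (highest value 9.99%, at d15), and the lowest UMI count per cell was 2576 at d0 and 2572 at d22 but 1322 at d15 and 1266 at d36. The cell names carry the day but not the library, so all cells of a day formed 1 pooled sample and no spread between libraries or animals was measured. With 1 pooled sample per day there was no test of any difference between days, and no p-value was computed. Intervals cover counting error only. They take each UMI as independent and do not cover the spread between cells, so they are too narrow for genes whose UMIs lie in few cells.

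The table held 9036 cells and 28692 gene symbols, of which 10850 had no UMI in any cell. Cells with at least 300 genes and at most 10% mitochondrial UMIs were kept, which left out 19 cells (3 at d15 and 16 at d36). Scrublet scoring in scanpy called 25 of 9017 cells doublets (0.277%), a share so low that the caller cannot be taken to have worked. Those cells were left out, and other doublets remain among the cells counted. Counts were log-normalised, 2000 variable genes and 30 principal components were taken, and cells were grouped over 15 neighbours by the Leiden method at resolution 1.0 into 20 clusters (scanpy 1.11.5, leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 on Python 3.11.15). Clusters were named from marker lists by their mean marker level, and clusters that carried the leading genes of other cell types were left out (141 cells). The 10 genes with the highest fold over the other cells were read for each cluster.

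Several cluster rules were set after the cluster output had been seen. A leading gene had to be detected in at least 25% of the cluster's cells. Clusters with Malat1, a nuclear RNA, below 25% of the level in the median cluster were kept out of the named classes as Malat1-poor cells, and clusters stayed unnamed if they had more leading genes from another marker list than from their own, or if they had none from their own. The general capillary class was exempt from the last rule, so that clusters led by other kinds of genes could belong to it. Another 7 cells in endothelial clusters took at least 2% of their UMIs from the markers of another cell type and were left out. In all, 8844 cells remained as EC.

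For each day, UMIs were summed over EC and divided by the day's EC total to give CPM (counts per 10⁶ UMIs). A ratio between 2 days has a 95% interval from the exact binomial comparison of both counts. A gene counted as measured with at least 50 CPM in either day and at least 200 UMIs over both, and met the size rule with a ratio of at least 1.5 in either direction and an interval that excluded 1. The later days were each set against d0, and d22 against d15 and d36 against d22 were read as steps. For 25 gene lists, the median log2 ratio of members with at least 10 CPM in either day was taken with 1 CPM added to each value, and placed as a percentile among 10000 random lists of the same size drawn from 20 bins of mean expression. That percentile describes these samples and is not a test. Shares of cells have Clopper-Pearson 95% intervals. A count of 0 was given a floor of 3 counts. Classes of EC were compared only with at least 50 cells in both days, which left out venous cells at d36.

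The gene lists, the marker lists, the size rule, the comparisons and the rule for named genes were fixed before the data were examined. That rule named, for each later day against d0, the 8 highest and 8 lowest ratios past the size rule, for each step 4 and 4, for each class 3 and 3, the 2 members of each list with the largest ratio in either direction, and 9 genes at every day: Lrg1, Angpt2, Tek, Sele, Selp, Vcam1, Icam1, Apln and Xist. Predicted genes, mitochondrial genes and immunoglobulin genes were kept out of the highest and lowest ratios. Not every gene the rule named is printed. Further list members given as examples, and genes named under added lists, were chosen after their values had been seen.

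Ratio and list code was checked on counts simulated from these samples. They were Poisson draws around the pooled means without spread between cells or animals, so the check covers counting error only. For d15 against d0, over 3505 measured genes, 100% of the 67 genes changed 2-fold and of the 66 changed 4-fold met the size rule, while 0 of the 67 changed 1.25-fold and 0 of 3305 unchanged genes did. The same shares were found for d22 against d0 over 3429 genes, with 0 of 3229 unchanged genes past the rule. For d36 against d0, over 3458 genes, 22.4% of the genes changed 1.25-fold also met it. Of 100 unchanged lists, 5, 1 and 8 fell outside the central 95% of random lists in these 3 comparisons.

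Alternatives were edgeR TMM scaling (edgeR 4.0.16) and DESeq2 size factors (DESeq2 1.42.0, R 4.3.3) in place of totals, no filter on low genes, a 2-fold rule, other cell filters, all cells in place of EC, doublet calls kept, classes weighted to the same shares, and every cell thinned to 1300 UMIs (which left out 11 d36 cells). Weighting used only classes with cells at every day, so the proliferating class, empty at d15, was left out of it on every day. Other resolutions (0.5 and 2.0) and clustering without genes that differed between days were tried for shares. Added after the data had been seen were a restriction to cells with at least 2576 UMIs, the common minimum, settings that left out low-UMI clusters, a cluster led by Fabp4, or pseudogene, predicted and ribosomal genes, a setting that kept cells with UMIs of other cell types, and thinned cells for the gene lists. The planned fits on single libraries were not run.

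Gene positions come from GENCODE M21 on GRCm38, the same assembly as mm10, in which 27337 of the 28692 symbols were found. Processed pseudogenes and close paralogs share sequence with their parent genes, and antisense genes overlap others, so that reads can be divided between them in ways not given in the sources used here. Values of such genes are reported as uncertain. Figures were drawn with matplotlib 3.10.9.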

Results

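The data comprised UMI counts of single lung EC at 4 days: d0 (wild-type mice), d15 (primary tumour), d22 (after resection) and d36 (metastases). The day totals over EC were 22729984 UMIs in 2617 cells at d0, 6844006 in 1475 cells at d15, 27492732 in 3179 cells at d22 and 6651608 in 1573 cells at d36. Depth per cell moved with the day, with median UMI counts of 7634, 4132, 7662 and 3399 and median gene numbers of 1353, 830, 1334 and 710. Each day was 1 pooled sample, so the differences between days have no replicate check, and every interval covers counting error only. Differences of d15 and d36 from d0 and d22 go together with a difference in depth.

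General capillary-like cells, the capillary EC that express Gpihbp1 and Plvap, made up the largest class of EC at each day. They were 62.0% of EC at d0 (95% interval 60.1 to 63.9), 69.7% at d15 (67.3 to 72), 64.5% at d22 (62.8 to 66.1) and 66.1% at d36 (63.7 to 68.5). Aerocyte-like cells, the wide capillary EC with Car4 and Ednrb, held 17.2% at d0, 11.9% at d15, 17.1% at d22 and 15.1% at d36. Arterial-like cells (Bmx, Mgp) held 6.08%, 5.29%, 6.67% and 4.01%, and venous-like cells (Slc6a2, Car8) held 5.04%, 4.07%, 4.03% and 2.35%. Lymphatic-like cells (Ccl21a, Mmrn1) numbered 22, 12, 19 and 3, and 26, 17, 27 and 14 when genes that differ between days were left out of the clustering. Cells led by proliferation genes such as Birc5 and Top2a numbered 27 at d0, 18 at d22 and 4 at d36, and 0 of 1475 cells at d15, where a floor of 3 cells would be 0.203%. Malat1-poor cells, kept out of these classes, were 6.34%, 3.73%, 3.99% and 8.96% of EC, and cells of unnamed clusters 1.41%, 4.54%, 2.61% and 2.99%. These are shares of a sort on EC, at unequal depth and with lowest UMI counts of 2576, 1322, 2572 and 1266. Shares also depended on the clustering and the cell filters, which the intervals do not cover. Arterial-like cells at d0 held 2.83% at resolution 0.5 and 6.75% at resolution 2.0. General capillary-like cells at d0 held 48.0% with stricter cell filters and 67.8% without genes that differ between days. At d22 they held 49.1% with doublet calls kept.

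**Figure D1:**
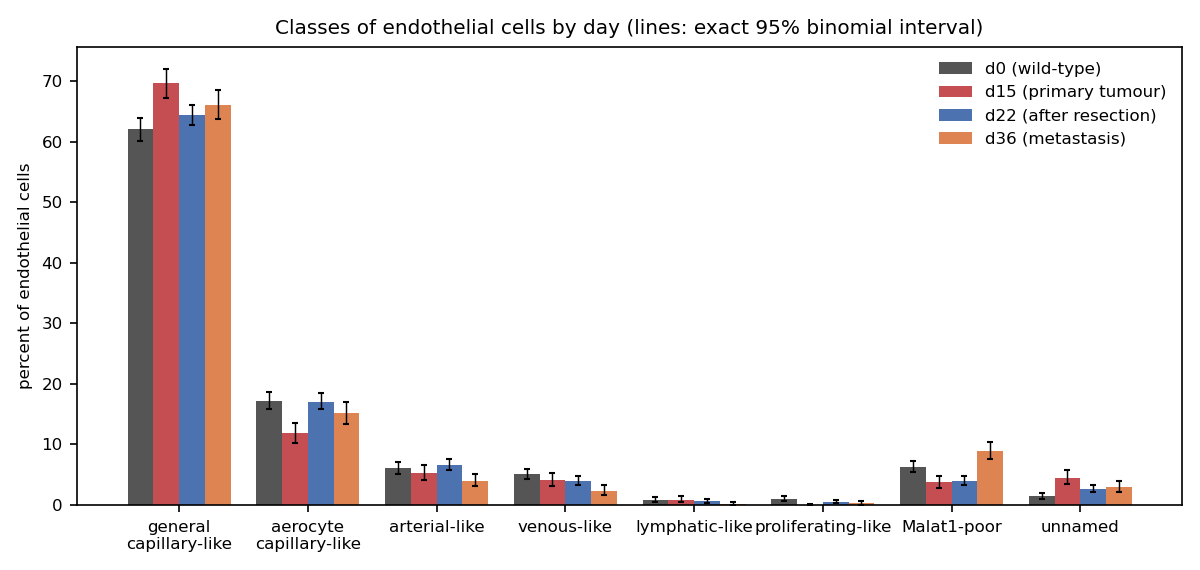
Share of endothelial cells (percent, vertical axis) in each class at the 4 days, with exact 95% binomial intervals as lines. In the clustering shown, general capillary-like cells lie between 62.0% and 69.7%, and aerocyte-like cells between 11.9% and 17.2%.

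The general capillary-like class joined several clusters whose weights differed by day. Its largest cluster at d0 was led by Slc6a6 and Wfdc1 (24.5% of EC), and at d15 by Lpl and Cadm1 (30.3%). A cluster of low UMI counts led by Hmcn1 and mitochondrial genes was large at d15 and d36 (19.9% and 21.5%). Other clusters of this class were led by MHC class II genes such as Cd74, by interferon-induced genes such as Ifit3 and Ifit1, or by early response genes such as Atf3 and Egr1. Aerocyte-like cells at d36 lay mostly in a cluster of low UMI counts led by Tbx2 and Lmo7 (10.4% of EC), and at d0 and d22 mostly in the cluster led by Fibin and Chst1 (14.1% and 14.0%).

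Markers of other cell types stayed low among the EC that were counted. Pan-leukocyte markers summed to 6.91, 3.07, 5.75 and 9.17 CPM, and macrophage markers to 14.9, 13.4, 21.0 and 24.5 CPM. T and NK cell markers summed to 2.33, 0.731, 0.436 and 1.05 CPM, and B cell markers to 1.80, 1.75, 1.67 and 14.3 CPM. Fibroblast markers reached 9.06, 2.78, 7.27 and 10.8 CPM, mural cell markers 17.9, 16.8, 25.2 and 29.3 CPM, and mesothelial markers at most 0.291 CPM. Epithelial markers summed to 88.9, 63.1, 147 and 137 CPM, mainly from Sftpc, the surfactant gene of alveolar type II cells, at 54.8, 37.6, 88.0 and 110 CPM. The monocyte and neutrophil list summed to 241, 298, 216 and 253 CPM, of which Plac8, a gene that also led arterial-like cells, held 221, 228, 200 and 190 CPM. Erythroid and platelet markers summed to 16.4, 41.8, 21.1 and 24.1 CPM. Median mitochondrial shares per cell were 1.88%, 1.95%, 1.61% and 2.85%, and ribosomal protein genes took 7.31%, 6.57%, 7.18% and 7.41% of UMIs.

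The comparison of d15 with d0 asked how lung EC differed while a primary tumour grew elsewhere in the body. Lrg1, a secreted glycoprotein of the acute phase that acts on TGF-β signalling, stood at 282 CPM at d15 against 136 CPM at d0, a ratio of 2.07 (1.95 to 2.19). Cd74, the invariant chain of MHC class II, was 3.30-fold lower (985 to 299 CPM), and Cyp1a1, a xenobiotic-metabolising enzyme and target of the aryl hydrocarbon receptor, was 34.7-fold lower (1201 to 34.6 CPM, 30.5 to 39.6). Esm1, a gene of endothelial tip cells that led the arterial-like cluster here, was higher by a ratio of 2.16 (1.92 to 2.44). Apln, the ligand of the apelin receptor, was lower at 0.534 (0.481 to 0.590) of its d0 level. The angiogenesis list, which holds both genes, lay inside the range of random lists. Its medians against d0 were 0.14, 0.04 and −0.06 at d15, d22 and d36. Vcam1, an adhesion molecule for leukocytes, lay at 0.596 (0.537 to 0.660) of d0, and Thbd, the anticoagulant receptor thrombomodulin, at 0.602 (0.583 to 0.622).

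Genes of the STAT3 and acute-phase list were higher as a group at d15, with 12 of 14 measured members above 1 and a median log2 ratio of 0.60, the 100th percentile of random lists. Lrg1, Bcl3 (2.08), Pim1 (1.61) and Stat3 (1.54) met the size rule, and Ackr1, a scavenger of chemokines, had 2.78 (2.11 to 3.64) at 14.9 CPM, but 0.413 without a cluster of 50 cells led by Fabp4. Ackr1 was detected in only 10 cells at d0 and 9 cells at d15. All 9 measured Notch pathway genes lay above 1 (median 0.46), among them Jag1 at 2.37, Dll1 at 1.78, Hes1 at 1.52 and Nrarp at 1.51. The BMP and TGF-β list had 15 of 16 members above 1 (median 0.30), with Smad6, an inhibitory SMAD, at 1.73. Early response genes (median 0.22, Dusp1 1.56, Atf3 0.680), lipid handling genes (median 0.23) and glucocorticoid-induced genes (median 0.26, Sgk1 1.43, Zbtb16 0.647) also lay above the central 95% of random lists. With classes weighted to the same shares, the lipid and glucocorticoid medians became 0.12 and 0.17, inside that range.

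Lists below that range at d15 were proliferation (median −0.80, 14 of 16 below 1), MHC and antigen presentation (median −0.20, 14 of 18 below 1) and ribosomal proteins (median −0.20, 72 of 102 below 1). The ribosomal list holds pseudogenes too, and its 11 members past the size rule were all higher. With all detected members the MHC median became −0.14, inside the range. Of the proliferation genes Birc5 had 2 UMIs at d15, a ratio of 0.0196 (0.00236 to 0.0713), and Ube2c 3 UMIs, a ratio of 0.0295 (0.00605 to 0.0869). These became 0.25 and 0.187 with classes weighted to the same shares, a setting that left out the proliferating class because it held 0 cells at d15. Hmgb2 (0.527) and Stmn1 (0.665) met the size rule. Besides Cd74, H2-Aa (0.589), H2-DMb1 (0.594), H2-DMa (0.603) and H2-Eb1 (0.621) were lower. Coagulation genes had a median of −0.20, within the range of random lists, with Plat, the tissue plasminogen activator, at 1.78. Cxcl10, an interferon-induced chemokine, had a ratio of 0.0578 (0.0211 to 0.127), and of 0.108 with thinned cells. Its UMIs lay in 44 cells at d0 and 2 cells at d15. Other members with the widest ratios of their lists were Nos3 (1.60), Vwa1 (2.21), Lamc1 (0.730), Jam3 (1.49), Cgnl1 (0.763, and 0.460 thinned), Hsph1 (1.93), Hspb1 (0.709), Pdk1 (1.49), Vegfa (1.47), Bhlhe40 (2.02), Ciart (1.75), Hsp90b1 (0.670), Pdia4 (1.33), Ccng1 (0.421), Trp53inp1 (0.584), Ifi27l2a (0.268), Rsad2 (0.583) and Nfkbie (0.564).

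Over the 3712 genes measured at d15 and d0, 150 met the size rule as higher and 87 as lower, a split that became 130 and 118 with TMM scaling. The highest ratios also included Ly6c2 (3.52), Milr1 (3.13), Egfl8 (3.05) and Wdr12 (2.85), and 3 genes that share sequence with ribosomal protein genes and are therefore uncertain, Rps18-ps3 (4.28), Rps27rt (2.78) and Rpl7a-ps5 (2.73). Ly6c2 is a close paralog of Ly6c1, so its value is uncertain as well. Fabp4, a fatty acid-binding protein, had a ratio of 3.52 (3.26 to 3.8), of 1.75 with classes weighted to the same shares and of 0.851 without the cluster it leads. It was detected in 161 cells at d0 and 56 cells at d15. The lowest ratios also included AY036118 (5.19-fold lower), a non-coding gene that overlaps Gm42418 and is therefore uncertain, Gpx3 (3.61-fold lower, 0.277, and 0.428 with all cells), Sox18 (2.55-fold), Cav2 (2.41-fold), Lbr (2.26-fold) and Cdkn2b (2.12-fold). Haemoglobin Hbb-bs stood at 14.6 against 6.64 CPM (2.20), and at 0.466 with all cells.

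**Figure D2:**
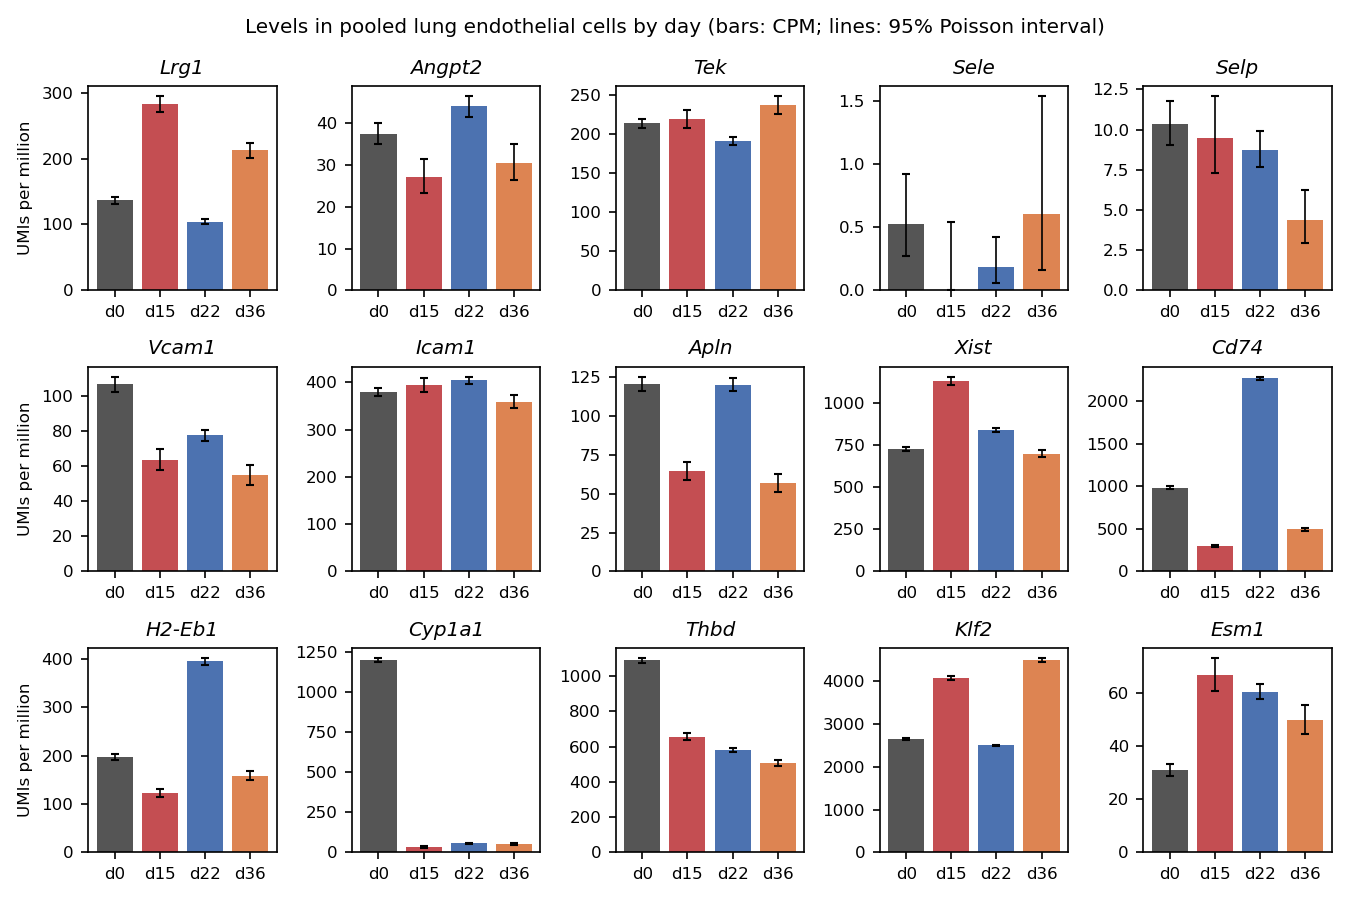
Level of 15 genes (CPM, vertical axes starting at 0) in endothelial cells at d0, d15, d22 and d36, with exact 95% Poisson intervals as lines. Lrg1 stands at 136, 282, 104 and 212 CPM and Cd74 at 985, 299, 2267 and 494 CPM.

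The comparison of d22 with d0 asked what lung EC held after the primary tumour had been removed, and it joined samples of near-equal depth. MHC class II genes, which present extracellular antigen to CD4 T cells, were higher at d22. Cd74 stood at 2267 against 985 CPM, a ratio of 2.30 (2.27 to 2.34), H2-Eb1 at 2.0 (1.93 to 2.07), H2-DMa at 1.92, H2-Aa at 1.91, H2-Ab1 at 1.83 and H2-DMb1 at 1.75. All 18 measured members of the MHC and antigen presentation list lay above 1, with a median log2 ratio of 0.46, the 100th percentile of random lists. Class I genes in it differed less, with H2-K1 at 1.37, B2m at 1.28 and H2-D1 at 1.27, and Ciita, the master regulator of class II, had 1.08. Epithelial Sftpc was also higher at d22, at 88.0 against 54.8 CPM (1.61), and at 4.34 with all cells. It did not follow the class II genes over the days, since it stood at 110 CPM at d36, where Cd74 was lower than at d0.

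Cyp1a1 was again lower, at 57.0 CPM against 1201 CPM (21.1-fold), and Thbd lay at 0.532 (0.522 to 0.543) of its d0 level. Lrg1 was lower than at d0, at 104 CPM and a ratio of 0.763 (0.725 to 0.803), while Esm1 was higher at 1.96 (1.79 to 2.14). Coagulation genes lay below 1 in all 10 measured members (median −0.26, Pros1 0.691), and so did heat shock genes (median −0.25, Hsph1 0.340, Hspa1a 0.544) and genes of basement membrane and matrix (median −0.19, Itga5 0.666, Bgn 0.775). Lower medians were also found for glucocorticoid-induced genes (−0.30, Tsc22d3 0.684, Sult1a1 0.725), proliferation (−0.19, Cenpf 0.460, Cdk1 0.479), mitochondrial transcripts (−0.16), junctions (−0.13, Ctnnb1 0.744) and ribosomal proteins (−0.02). Higher medians were found for BMP and TGF-β genes (0.14, Ltbp1 1.32) and for ER stress genes (0.10, Atf4 1.18). With classes weighted to the same shares, and the proliferating class thereby left out, Cdk1 lay at 0.223. The proliferation and ribosomal medians then became −0.09 and 0.00133, inside the range of random lists. With thinned cells the ER stress median (0.06) also fell inside it.

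The STAT3 and acute-phase list had a median of −0.04 at d22, and Notch genes a median of 0.02 with Dll1 at 0.587 and Jag1 at 0.777. Other list members with the widest ratios were Fgl2 (0.569), Ifi27l2a (0.645), Ifit1 (0.794), Vcam1 (0.727), Cxcl12 (1.29), Birc3 (1.14), Aplnr (0.702), Tie1 (0.754), Cgnl1 (0.804), Cav2 (0.684), Lpl (0.864), Ier3 (1.14), Rhob (1.14), Adm (1.37, and 0.929 with thinned cells), Ndrg1 (0.809), Cry1 (0.609), Bhlhe40 (0.813), Xbp1 (1.13), Ccng1 (0.543) and Cdkn1a (0.763). Of 3561 measured genes, 9 met the size rule as higher and 60 as lower. The lowest ratios also included AY036118 (3.16-fold lower), Sun1 (2.44-fold), Lbr (2.40-fold), Sh3tc1 (2.25-fold), Ddb1 (2.14-fold), Dctn1 (2.08-fold) and Npr1, a natriuretic peptide receptor (1.93-fold).

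**Figure D3:**
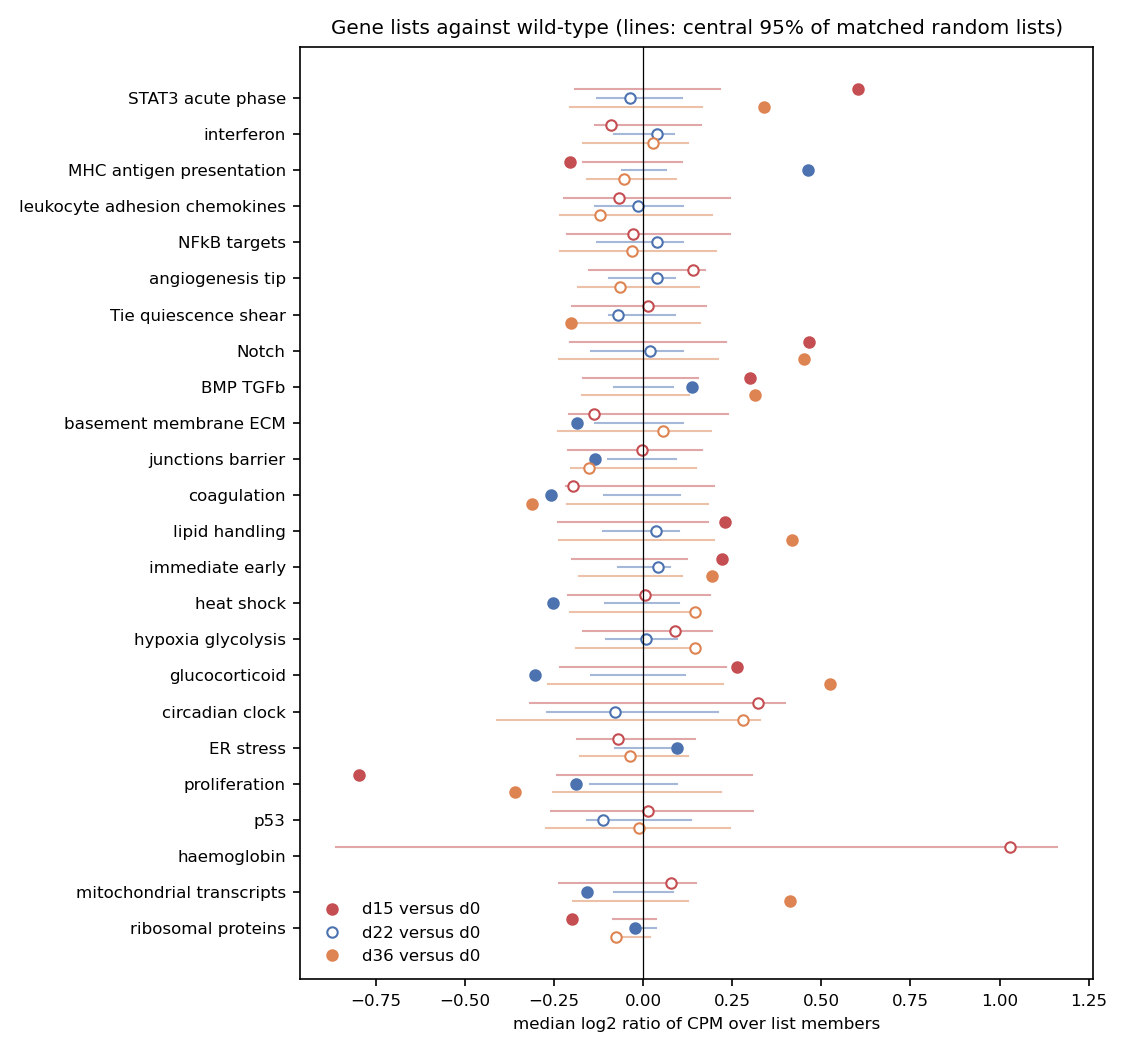
Median log2 ratio of each gene list (horizontal axis) at d15, d22 and d36 against d0. Lines span the central 95% of random lists and filled points lie outside it. The MHC and antigen presentation list lies at −0.20, 0.46 and −0.05, and the STAT3 and acute-phase list at 0.60, −0.04 and 0.34.

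The comparison of d36 with d0 concerned mice that bore metastases. Klf2, a transcription factor that responds to shear stress, stood at 4490 against 2642 CPM, a ratio of 1.70 (1.68 to 1.72), and Lrg1 at 212 against 136 CPM, a ratio of 1.56 (1.46 to 1.66). Aplnr, the apelin receptor, lay at 0.397 (0.364 to 0.432) of its d0 level, Apln at 0.469, Thbd at 0.466 and Pros1, the anticoagulant protein S, at 0.503. Cd74 lay at 0.501 (0.483 to 0.520), and Cyp1a1 was 23.9-fold lower at 50.2 CPM. Hspa1a, an inducible heat shock protein, was higher at 2.22 (2.04 to 2.42).

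Glucocorticoid-induced genes had a median log2 ratio of 0.53 at d36 (7 of 9 members above 1), with Sult1a1 at 1.90, Tsc22d3 at 1.66 and Per1 at 2.93, which became 1.67 with stricter cell filters and 5.72 with thinned cells. Notch genes lay above 1 in all 9 measured members (median 0.45, Jag1 2.06, Nrarp 1.40), none of which met the size rule. Of 14 STAT3 and acute-phase genes 12 lay above 1 (median 0.34). BMP and TGF-β genes had a median of 0.31 (12 of 16 members above 1), with Smad6 at 1.69, the receptor Bmpr2 at 1.59 and Skil at 1.54. In this list 3 members met the size rule as higher and 1 as lower. Early response genes (median 0.19, Dusp1 1.60, Ier2 1.43) and lipid handling genes (median 0.42, Cav2 0.391) lay above the central 95% as well. In the last list Tcf15 had 2.79, and 0.877 without the Fabp4-led cluster. Mitochondrial transcripts had a median of 0.41 with mt-Co3 at 1.60, while median mitochondrial shares per cell were also higher at d36, and mt-Nd6 at 3.48 became 1.56 with stricter cell filters. Against this direction mt-Atp8 lay at 0.378, and at 0.206 with stricter cell filters. The mitochondrial median became 0.11 above the common UMI minimum, the glucocorticoid median 0.11 with all detected members and the lipid median 0.21 with thinned cells, each inside the range of random lists.

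Lower lists at d36 were coagulation (median −0.31, 8 of 10 members below 1), proliferation (−0.36, Mcm5 0.212, Rrm2 0.351, and 0.162 with thinned cells) and genes of Tie receptors and shear response (−0.20, despite Klf2). The last median became −0.14 above the common UMI minimum and the proliferation median −0.21 with weighted classes, both inside the range of random lists. The weighted setting left out the proliferating class. Vcam1 lay at 0.514 and Bgn at 0.465, which became 0.848 and 0.721 with classes weighted to the same shares. Ackr3, a scavenging chemokine receptor, lay at 0.449, Nrp1 at 0.622, and Hsp90b1, a chaperone of the endoplasmic reticulum, at 0.621. Further members with wide ratios were Fgl2 (0.291, and 0.514 weighted), Ifi27l2a (0.511), Ifih1 (0.515), H2-DMb1 (0.678), Cxcl10 (0.337, and 0.863 thinned), Nfkbie (0.422, and 0.258 thinned), Adm (2.63, and 6.43 weighted), Vwa1 (1.85), Cgnl1 (0.536, and 0.341 thinned), Jam3 (0.636), Hspb1 (0.7), Vegfa (1.42), Arntl (1.44), Calr (0.752), Ccng1 (0.673) and Cdkn1a (1.45). Ackr1 had 3.50, and 0.213 without the Fabp4-led cluster.

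Of 3652 genes measured at d36 and d0, 154 met the size rule as higher and 120 as lower, a split that became 106 and 120 without pseudogenes, predicted genes and ribosomal protein genes. The 8 highest ratios included 6 genes that share sequence with ribosomal protein genes and are uncertain, Rps18-ps3 (6.08), Rps27rt (4.99), Rpl36-ps3 (3.77), Rpl13-ps3 (3.09), Rpl13a-ps1 (2.78) and Rpl23a-ps3 (2.76). The other genes among them were Wdr89 (3.19) and Ly6c2 (3.18). Ccl21a, a chemokine of lymphatic EC, was 6.63-fold lower, at a ratio of 0.151 that became 0.571 with weighted classes and 0.0180 with stricter cell filters, and lymphatic-like cells numbered 3 at d36, or 14 when genes that differ between days were left out of the clustering. AY036118 was 3.19-fold lower, Cmtm6 2.89-fold, Slc38a10 2.61-fold, Pcolce2 2.61-fold and Antxr2 2.60-fold. Hypoxia and glycolysis genes, heat shock genes and circadian clock genes had medians of 0.15, 0.15 and 0.28 at d36, inside the range of random lists. The interferon list had medians of −0.09, 0.04 and 0.03 at d15, d22 and d36, the leukocyte adhesion and chemokine list −0.07, −0.01 and −0.12, and NF-κB targets −0.03, 0.04 and −0.03, all inside that range.

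**Figure D4:**
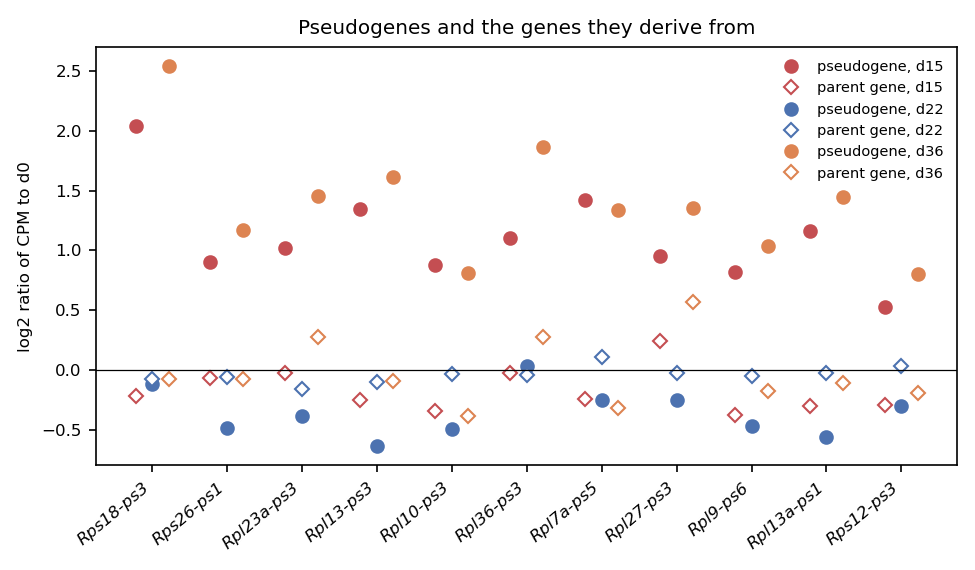
Log2 ratio of CPM to d0 (vertical axis) at d15, d22 and d36 for 11 ribosomal protein pseudogenes and their parent genes. The levels behind the ratios at d0, d15, d22 and d36 are 19.6, 84.0, 18.0 and 119 CPM for Rps18-ps3. For its parent Rps18 they are 1442, 1238, 1370 and 1365 CPM.

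Over the step from d15 to d22, in which the tumour was removed and depth also differed, Cd74 was 7.59 times its d15 level (7.26 to 7.93), H2-Aa 3.24 times and H2-Eb1 3.22 times. Sox18, a transcription factor of vessel development, had a ratio of 3.55. Lrg1 lay at 0.369 (0.348 to 0.391) of its d15 level, Dll1 at 0.329, Bcl3 at 0.493 and Stat3 at 0.625, and Apln was higher at 1.87 (1.69 to 2.07). All 18 measured MHC and antigen presentation genes lay above 1 (median 0.67), and 12 of 13 STAT3 and acute-phase genes below it (median −0.50). All 9 Notch genes lay below 1 (median −0.37). Of 3694 measured genes, 68 met the size rule as higher and 213 as lower, a split that became 97 and 168 with TMM scaling and 90 and 171 with DESeq2 size factors. The lowest ratios were those of Rps18-ps3 (4.66-fold lower), Ly6c2 (4.46-fold), Rpl13-ps3 (4.03-fold) and Fabp4 (3.52-fold lower, a ratio of 0.284 that became 0.457 with weighted classes and 0.675 without the Fabp4-led cluster).

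Over the step from d22 to d36, Cd74 was 4.59-fold lower and all 18 measured MHC and antigen presentation genes lay below 1 (median −0.47). Lrg1 was higher at 2.04 (1.91 to 2.17), Hspa1a at 4.08 (3.71 to 4.49), Tsc22d3 at 2.42 and Klf2 at 1.80, and Apln lay at 0.471. Mitochondrial mt-Co3 (1.79) and mt-Cytb (1.71) were higher, and so was the median mitochondrial share per cell. Ccl21a was 3.69-fold lower (0.271, and 0.740 with weighted classes, and 0.0332 with stricter cell filters), Pcolce2 2.88-fold and Cdkn2b 2.65-fold. The uncertain genes Rps18-ps3 (6.61), Rpl13-ps3 (4.85) and Rpl13a-ps1 (4.15) had the highest ratios. Of 3635 measured genes, 212 met the size rule as higher and 93 as lower.

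Genes of the vessel's inflammatory and angiogenic state were followed at every day. Angpt2, the antagonist ligand of the receptor Tie2, stood at 37.4, 27.2, 44.0 and 30.5 CPM, and Tek, which encodes Tie2, at 214, 219, 191 and 238 CPM. Sele, an inducible selectin, was almost undetected, with 12, 0, 5 and 4 UMIs, too few to compare. Selp stood at 10.3, 9.50, 8.73 and 4.36 CPM (0.422 at d36 against d0, and 0.172 with stricter cell filters). Vcam1 stood at 107, 63.6, 77.5 and 54.9 CPM, Icam1 at 380, 394, 404 and 359 CPM, and Apln at 121, 64.4, 120 and 56.7 CPM. Xist, transcribed from the inactive X chromosome of female cells, stood at 730, 1134, 841 and 700 CPM, and none of the 4 Y-linked genes reached the level needed to enter a list median.

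Several of these differences were also present within classes of EC. In general capillary-like cells Lrg1 had ratios to d0 of 1.69 (1.54 to 1.85), 0.798 and 1.88 at d15, d22 and d36, and in aerocyte-like cells of 1.75 (1.34 to 2.27), 0.834 and 2.43. In venous-like cells, where its level was highest among the classes compared at 1055 CPM at d0, Lrg1 had 1.56 (1.42 to 1.71) at d15 and 0.779 at d22. Thbd in general capillary-like cells lay at 0.623, 0.557 and 0.465 of d0, and Klf2 at 1.60, 0.939 and 1.82. Vcam1 in arterial-like cells lay at 0.458, 0.546 and 0.549. Esm1, a gene that leads the arterial-like cluster, is not compared within it. Apln in aerocyte-like cells, which hold most of it, had 0.841 (0.755 to 0.935), 1.04 and 0.629 (0.556 to 0.709). The general capillary-like class joined clusters in other proportions at each later day than at d0, and the aerocyte-like class did so at d15 and d36, with more cells of low UMI counts at these days.

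At d22, Cd74 was higher in general capillary-like cells (2.32, 1503 to 3484 CPM), venous-like cells (2.42), arterial-like cells (2.71) and aerocyte-like cells (1.81, 82.3 to 149 CPM). The general capillary-like class held a cluster led by Cd74, H2-DMa and H2-Eb1 at 4.01% of EC at d0 and 13.8% at d22, and the cluster led by Slc6a6 at 24.5% and 13.2%, so its ratios join level and mix. H2-Eb1 (1.99) and H2-DMa (1.98) in general capillary-like cells and H2-Ab1 in venous-like cells (2.43) were higher as well. In aerocyte-like cells Iigp1, an interferon-induced GTPase, had 2.21 and Gpx7 1.84, and in arterial-like cells Scgb3a1 had 4.09 and Med21 2.52 while interferon-induced Ifit1 and Ifit3 were 4.29-fold and 3.76-fold lower. Rassf9 had 2.35 in venous-like cells. Pald1 was 2.87-fold lower in aerocyte-like cells and Npr1 2.5-fold lower in venous-like cells, and Sun1 was 2.67-fold lower in general capillary-like cells.

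At d15, arterial-like cells held more Eln, the gene of elastin (2.73, 2.24 to 3.33), and venous-like cells more Smad7, an inhibitory SMAD (2.60), and Arl4d (2.65), with Lurap1l 5.84-fold and Apoa1bp 3.66-fold lower. Milr1 had 3.49 in general capillary-like cells and Rnaset2b, a gene with a near-identical copy, 3.21 in aerocyte-like cells. At d36, arterial-like cells held more Stx7 (2.54) and less Trim35 (4.98-fold) and Hbp1 (4.48-fold), and aerocyte-like cells less Wdr74 (7.76-fold, 4.04 to 17.1) and Ces2e (7.14-fold). Cmtm6 was 3.31-fold lower in general capillary-like cells. In the pair of capillary classes, 196 genes met the size rule as higher and 100 as lower at d15 in general capillary-like cells, and 296 and 243 in aerocyte-like cells. At d22 the counts were 15 and 62, and 22 and 97, and at d36 they were 174 and 128, and 320 and 306. Genes measured numbered 3718 and 3699 at d15, 3555 and 3499 at d22, and 3661 and 3664 at d36. Aerocyte-like sums were smaller, with 1181512 UMIs at d15 and 1187186 at d36 against 4348607 and 4321653, which widens counting error. That class also held more cells of low UMI counts at d15 and d36 than at d0. The counts therefore do not rank the classes.

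Positions refer to GRCm38. Lrg1 lies at chromosome 17:56119678-56122001, Cd74 at 18:60803848-60812652, H2-Eb1 at 17:34305867-34316674, H2-Aa at 17:34282744-34287823 and Cyp1a1 at 9:57687928-57703824. Apln lies at X:48025146-48034853, Esm1 at 13:113209659-113218098, Thbd at 2:148404466-148408188 and Klf2 at 8:72319033-72321656.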

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

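All tests in this part were chosen after the results had been seen. MHC class II genes had opposite directions against d0 at d15 and d22, and this contrast between days was what singled them out. Cd74 lay at 0.303 of d0 at d15 and at 2.30 at d22, H2-Eb1 at 0.621 and 2.0, H2-Aa at 0.589 and 1.91, H2-DMa at 0.603 and 1.92, and H2-DMb1 at 0.594 and 1.75. Cd74 lay at 0.501 at d36. Dll1, a Notch ligand, had 1.78 at d15 and 0.587 at d22, Hspa1a, a heat shock protein, 0.544 at d22 and 2.22 at d36, and Rpl13-ps3, a pseudogene, 2.56, 0.637 and 3.09 at d15, d22 and d36. Between capillary classes, Wdr74 at d15 had 1.64 (1.39 to 1.93) in general capillary-like cells and 0.662 (0.475 to 0.902) in aerocyte-like cells. Pde4b at d36 had 1.57 (1.46 to 1.68) and 0.636 (0.517 to 0.776), and Zbtb7a at d36 had 1.56 (1.42 to 1.72) and 0.626 (0.502 to 0.774). These differences between days and classes were not tested, since each day is 1 pooled sample.

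For the higher class II genes at d22, 3 technical readings were set against a difference in the EC themselves. Free RNA from other cells would add alike to every class, but the gain of Cd74 in aerocyte-like cells (66.8 CPM) was 3.37% of that in general capillary-like cells (1980 CPM). Without cells that hold a pan-leukocyte UMI (18 at d0 and 20 at d22), the median ratio of the 6 class II genes was 1.91, against 1.92 with them. So few cells were left out that this shows only that those cells do not carry the difference. With the named classes weighted to the same shares the median ratio was 1.89, which argues against another mix of those classes. Inside the general capillary-like class, the cluster led by Cd74 held 4.01% of EC at d0 and 13.8% at d22, so another mix of cells within that class stays open. A difference between animals, pools or runs stays open, because group and pool cannot be separated.

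Lrg1 at d15 had a ratio of 2.03 (1.92 to 2.16) among cells above the common UMI minimum, so the cells below that minimum do not account for it. The cut sets only a minimum, and depth above it could still differ between days, so lower depth itself is not addressed. Without the Fabp4-led cluster the Lrg1 ratio was 1.72 (1.62 to 1.83), so that cluster accounts for part of the difference and not for all of it. At d36, which shares the low depth of d15, Lrg1 had 1.56 (1.46 to 1.66). That value met the bound written for a difference in runs or handling shared by d15 and d36, and a real difference at both days would give the same value, so this test cannot tell them apart.

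Ribosomal protein pseudogenes had a median log2 ratio to d0 of 0.99 at d15 and 1.35 at d36, and of −0.42 at d22. Their parent genes had medians of −0.25 at d15 and −0.09 at d36, as reads shared between pseudogene and parent and divided otherwise in these samples would give. Transcription of the pseudogenes themselves would give this too. At d22 the parent median was −0.04, the direction of the pseudogenes. At d36 the parents Rpl23a (936 to 1130 CPM), Rpl36 (873 to 1055 CPM) and Rpl27 (329 to 489 CPM) were higher than at d0, and the other parents were lower. The parents therefore cannot decide between these readings. With cells above the common UMI minimum the pseudogene medians were 1.00 and 1.42, so the cells below that minimum do not account for them. Lower depth above the minimum is not addressed by this cut. The days with higher pseudogenes are the days of low depth, and d36 against d15 gave a median of 0.28, with 0.16 for the parents.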

How the results depend on the processing

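No paired analysis was possible because the cell columns name no library, and each day has 1 pooled sample. The planned fits without each library, with a library block and with DESeq2 or edgeR tests on libraries were not run for the same reason. Among 223 ratios of named genes, Fabp4 was the only gene past the size rule whose ratio turned direction. Below the rule, Ackr1, Tcf15, Hbb-bs, Adm and Vcam1 (0.708 at d36 against d22, and 1.05 with thinned cells) turned, as did ratios of Tek, Sele, Selp, Apln and Icam1 close to 1. The value stayed inside its 95% interval for 215 with TMM scaling, 220 with DESeq2 size factors, 169 with stricter cell filters, 212 with all cells, 171 with weighted classes, 197 above the common UMI minimum, 176 without low-UMI clusters, 213 without the Fabp4-led cluster and 223 with doublet calls kept or without cell filters, and for 113 of 218 with thinned cells.

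Fabp4 at d15 against d0 had 0.851 without the cluster it leads, by construction of that setting. Of 117 list medians, 115 stayed inside the 95% interval of redrawn counts with a pseudocount of 5 CPM, 96 with all members, 85 with TMM scaling, 96 above the common UMI minimum, 92 with weighted classes and 60 with thinned cells. The ribosomal median at d22 against d0 became 0.00133 with weighted classes. At d22 against d15 the proliferation median became −0.0985 with weighted classes, a setting that left out the proliferating class on every day. The mitochondrial median became 0.0191 above the common UMI minimum. The cause of the ribosomal and mitochondrial changes was not tested.

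Genes meeting the size rule in the 5 comparisons (d15, d22 and d36 against d0, then the 2 steps) numbered 52, 9, 70, 76 and 83 with a 2-fold rule and 3101, 1907, 2948, 3097 and 2950 without the filter on low genes, both by construction. With thinned cells they numbered 387 at d15 against d0 and 422 at d22 against d15. The cause was not tested. The number of lists outside random lists stayed within 1.5 times under all alternatives run, but not always the same lists. With weighted classes 7 of 9 kept their place at d15 against d0 and 6 of 10 at d22 against d15, as did 6 of 10 in that step with thinned cells and 7 of 11 at d36 against d22 above the common UMI minimum.

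Shares of classes depended on the clustering. General capillary-like cells at d0, d15, d22 and d36 held 66.5%, 75.2%, 71.2% and 70.03% at resolution 0.5, 56.2%, 65.7%, 57.4% and 62.5% at resolution 2.0, and 67.8%, 76.9%, 71.8% and 71.3% without genes that differ between days. With doublet calls kept they held 56.8% at d0, 49.1% at d22 and 63.3% at d36, with stricter filters 48.0% at d0, 62.6% at d15 and 51.8% at d22, and above the common UMI minimum 68.8% at d36. Aerocyte-like cells held 18.8% at d0 and 13.8% at d15 with stricter filters. Arterial-like cells held 2.83%, 3.32%, 2.30% and 1.84% at resolution 0.5, 3.0%, 3.24%, 2.38% and 2.15% without genes that differ between days, 2.88%, 3.65%, 2.66% and 2.09% with stricter filters, and 5.64% at d36 above the common UMI minimum. Venous-like cells held 4.17% at d0 and 3.10% at d15 without those genes, 5.35% at d15 with stricter filters, and 5.37% at d15 and 3.38% at d36 above the common UMI minimum. Lymphatic-like cells held 0.884% at d36 and proliferating cells 0.645% at d0 without those genes, and proliferating cells 0.923% at d22 with stricter filters. The cause was not tested.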

Other observations

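The tests in this part, and the genes named in it, were chosen after the results had been seen. Cyp1a1 was lower than at d0 in every class compared. At d0 it stood at 882 CPM in general capillary-like cells, 2323 CPM in aerocyte-like cells, 496 CPM in arterial-like cells and 682 CPM in venous-like cells. It was 32.2-fold, 21.8-fold and 26.1-fold lower at d15, d22 and d36 in general capillary-like cells, and 34.7-fold, 28.7-fold and 24.4-fold lower in aerocyte-like cells. Arterial-like cells had 39.7-fold and 27.1-fold lower values at d15 and d22 and 0 UMIs at d36. With the floor of 3 counts in place of 0, the d36 value was 55.3-fold lower, and its interval reached down to 44.8-fold. Venous-like cells had 12.0-fold and 3.24-fold lower values at d15 and d22. Ahr, the receptor that induces Cyp1a1, stood at 156, 156, 168 and 138 CPM, and its targets Tiparp at 26.4, 32.6, 21.8 and 36.5 CPM and Nqo1 at 9.63, 5.11, 4.11 and 3.46 CPM. A list of 8 genes tied to this receptor had 3 measured members, with medians of −0.00296, −0.27 (percentile 1.8 of random lists) and −0.18. The 3 were Cyp1a1, which prompted the list, Ahr itself and Tiparp. Each median is thus the value of 1 gene, Ahr at d15 and d36 and Tiparp at d22, and says nothing of the receptor's targets as a group.

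A cluster of 50 EC was led by Fabp4, Igfbp3, C1qtnf9, Meox2 and Tcf15, genes of fatty acid handling and of capillaries outside the lung. It held 3, 16, 11 and 20 cells at d0, d15, d22 and d36. Lrg1 stood at 2159 CPM in it against 135 CPM in the other EC. The cluster held 86.2% of the Fabp4 UMIs and 19.4% of the Lrg1 UMIs of d15.

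The samples of d36 and d15 are near each other in depth. Of 3654 genes measured in both, 24 met the size rule as higher at d36 and 60 as lower. Hspa1a (2.83), Sult1a1 (1.94), Cd74 (1.65) and Hmgb2 (1.61) were higher at d36, and Ltbp4 (0.511), Fabp4 (0.563), Bgn (0.567), Dll1 (0.610) and Aplnr (0.628) were lower. STAT3 and acute-phase genes had a median of −0.26, angiogenesis genes −0.24 and coagulation genes −0.30, below the central 95% of random lists. MHC and antigen presentation genes had 0.15, mitochondrial transcripts 0.30, glucocorticoid-induced genes 0.22, p53 targets 0.22 and ribosomal proteins 0.13, above it. Notch genes had −0.10, BMP and TGF-β genes −0.06, lipid handling genes −0.06 and early response genes 0.06, all inside it. The medians of Notch, lipid handling and early response genes thus differ between the days of low and of high depth and less between d36 and d15. BMP and TGF-β genes also differed at like depth, with a median of 0.14 at d22 against d0, above the central 95%. Across unlike depth 237 (d15) and 274 (d36) genes met the size rule against d0, and 281 and 305 over the steps. Within like depth 69 (d22 against d0) and 84 (d36 against d15) did. A difference in runs or handling that goes with depth was not tested for these lists or genes.

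AY036118, at chromosome 17:39847113-39848035 on the minus strand, overlaps Gm42418 on the plus strand. Gm42418 stood at 607, 299, 271 and 422 CPM. Genes annotated as antisense had a median log2 ratio to d0 of 0.96 over 11 genes at d15, 0.05 over 8 at d22 and 0.66 over 10 at d36, and of these 7, 0 and 6 met the size rule as higher.

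A response to interferon gamma was put forward for the class II genes at d22, with a list of 16 other genes that this cytokine induces. The list had a median log2 ratio of 0.15 at d22 over 12 measured genes, 10 of them above 1, at percentile 99.8 of random lists. That median lies below the bound of 0.2 under which the explanation was to be set aside, but the spread of random lists (0.106) was then added to the bound, after the value had been seen, and with it the test cannot tell. At d15 the list had a median of −0.41 and at d36 of 0.27, where class II genes such as Cd74 were lower than at d0.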
